A study of Mus musculus with 5 samples.

How the data were processed

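The series holds 5 RNA-seq libraries, 1 per group, from mouse embryos at the 4-cell stage that were made by nuclear transfer, in which the nucleus of a donor cell is placed in an oocyte without its own nucleus. The strain is B6D2F1. The donor cell is not given in the sources used here. Total RNA was made into Illumina TruSeq libraries and sequenced as single reads of 51 bases, per the labels' protocols. The groups were taken from the labels: untreated embryos, embryos treated with luciferase, embryos with a knockdown of H3.3, and knockdown embryos given either H3.3 mRNA or H3.2 mRNA. H3.3 is the histone H3 variant encoded by H3f3a and H3f3b that is placed in chromatin outside of DNA replication, and H3.2 is a form of H3 made for replication. The labels of the last library conflict: its title and the series design name H3.2 mRNA, whereas its treatment tag names H3.3 mRNA. The title was used here, and each statement on the library labelled H3.2 mRNA depends on that choice. The source names also differ, NT for the untreated, knockdown and H3.3 mRNA libraries and SCNT for the luciferase and H3.2 mRNA libraries, and this was treated as a possible batch. Whether either split marks separate experiments is not given in the sources used here.

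The authors aligned reads with TopHat and estimated FPKM (fragments per kilobase of transcript scaled to the mapped reads) with Cufflinks on the mm9 build, per the submitters' processing notes, which give no versions. Each deposited file lists 1 FPKM value for each of 22026 gene symbols, and no symbol appears more than once. FPKM divides reads by transcript length and by the library's total, so a change in some abundant transcripts shifts the share left for all others, and transcripts with near-identical copies, such as ribosomal protein genes and histone genes with their pseudogenes, can trade reads. The sequencing depth is unknown. Values under 20 FPKM were searched for steps worth 1 read over 2132 genes, and no step was found, since the fullest bin of 0.1 log2 units between libraries held 3.42% of the genes. No interval or detection limit that needs a read count is therefore given. Many values are exactly 0: 732 genes were at 0 in the untreated library alone, 465 in the knockdown alone, 172 with H3.3 mRNA alone, 117 in the luciferase library alone and 70 with H3.2 mRNA alone. Such a gene is described as listed at 0, and no fold is given against it.

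Values were compared as log2(FPKM + 1), which understates the change of genes with low values, over the 13144 genes with a mean of at least 1 FPKM across the 5 libraries. With 1 library per group there is no replicate and no p-value. A gene was counted as higher or lower at a difference of at least 4-fold (2 on the log2 scale), and for the knockdown against both controls it had to pass against each control. The difference between the untreated and luciferase libraries was the measure of how far 2 control libraries lie apart. For the add-back libraries, a gene counted as back on the control side when its log2 value lay closer to the mean of the controls than to the knockdown. Such genes were picked for an extreme knockdown value, so some lie back by chance alone, and that share was not estimated for either add-back library.

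There were 27 gene lists, fixed before the data were examined, as were the groups, the thresholds, the comparisons, the rule for named genes and most of the alternatives. Of the 921 list members, 903 matched a symbol in the files, older symbols included. The median difference of a list was placed among 10000 random lists of the same size, each member drawn from the 200 genes nearest in mean level. A list stood apart under percentile 2.5 or over percentile 97.5, and needed 5 members past the filter. This describes these libraries and is no test. The 2 H3.3 genes and the 4 neural lineage genes past the filter were too few, and X-linked genes were added, which left 26 lists. Chromosomes came from a RefSeq table of the GRCm38.p6 assembly for 99.3% of the genes past the filter, and transcript length and GC content from the longest transcript per symbol of the GENCODE annotation of GRCm38 for 98.8%. No coordinate is printed, since these builds differ from mm9.

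Genes are named by a fixed rule that leaves out clone and model names: the 12 highest and 12 lowest for the knockdown among genes at least 4-fold from each control, the 10 highest and 10 lowest for comparisons that involve an add-back library with the knockdown or the other add-back library, the 5 highest and 5 lowest for other pairs, and up to 4 members of a list with the largest absolute difference. Because many of the genes so ranked are listed at 0 in a compared library, the same ranking over the 8537 genes above 0 in every library is used beside it, a choice made after the values were seen. Some genes that the rule names are not reported here. The alternatives tried were other pseudocounts, other filters, 3 rescalings, other folds, other nearest-gene numbers, each control alone and a stricter definition of back. Filters at 50 FPKM, removal of length and GC trends by running medians over 201 genes, and lists matched on length or GC content were added after the data were seen.

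All steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The counting and list steps were tested on simulated data, with 2 libraries of 13144 genes drawn around the luciferase library and 200 genes changed by 8-fold. They recovered 90% of the raised and 90% of the lowered genes and called 0.294% of the unchanged ones. Of unchanged lists 5% lay outside the percentiles, and all lists of 30 genes raised 2-fold were found. The simulated noise was a fixed setting, smaller than the spread in these data, where 36.9% of genes differed 4-fold between the 2 controls. These rates check the steps and are not error rates for these libraries. Removal of a simulated length trend moved its rank correlation with length from -0.56 to -0.013, and a list of short genes moved from percentile 100 to 89.7 once it was matched on length.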

Results

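Transcript levels were measured by RNA-seq in 5 libraries of mouse 4-cell embryos made by nuclear transfer, 1 library each for untreated embryos, embryos treated with luciferase, embryos with a knockdown of histone H3.3, and knockdown embryos labelled as given H3.3 mRNA or H3.2 mRNA. The labels name no replicate, so every value below comes from 1 library and no difference has a replicate check. The series title places the work in the question of what maternal H3.3 does when an oocyte reprograms a transferred nucleus. The sequencing depth is unknown. Of 22026 genes, 10443 were above 0 FPKM in the untreated library, 12300 in the luciferase library, 10496 in the knockdown library, 11280 with H3.3 mRNA and 12261 with H3.2 mRNA. Across the 13144 genes with a mean of at least 1 FPKM, the untreated library correlated least with the others, with Pearson's r across genes from 0.740 to 0.753, and the other pairs ranged from 0.799 to 0.835. Genes are not independent replicates.

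The knockdown target was examined first. H3f3a and H3f3b, the genes that both encode H3.3, stood at 783 and 4484 FPKM in the untreated library and at 3503 and 2230 FPKM in the luciferase library. In the library labelled H3.3 knockdown they stood at 128.5 and 535.2 FPKM. Their sum in the knockdown was 12.6% of the untreated and 11.6% of the luciferase level. The sum was 8.86% and 8.14% of those levels with H3.3 mRNA, and 7.98% and 7.33% with H3.2 mRNA. The sum was 5266 FPKM in the untreated and 5734 FPKM in the luciferase library, with the parts divided differently. It was 664 FPKM in the knockdown and 467 FPKM with H3.3 mRNA, so the target values do not show the H3.3 mRNA that the label of that library names. Whether the added mRNA lies outside these gene models, had decayed or was not delivered was not tested, and no value here shows its delivery. Both genes have near-identical pseudogene copies, so the division of reads between them is uncertain.

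**Figure D1:**
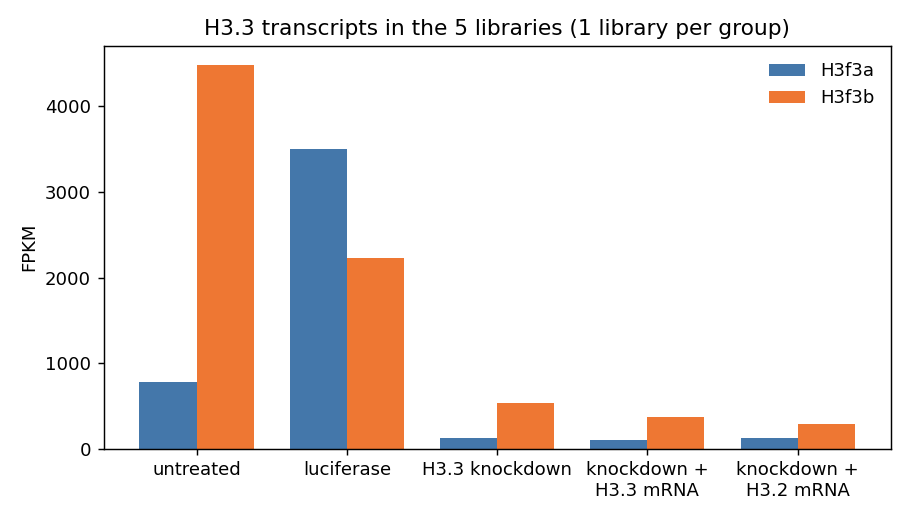
H3f3a and H3f3b in each library (y axis, FPKM, from 0; 1 bar per gene and library, no replicates). The 3 knockdown libraries lie at 535 FPKM or below for either gene, and the controls at 783 FPKM or above.

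The genes lower in the knockdown than in both controls were ranked, and Krt8 and Slc5a11 were among the leading ones. Krt8, a keratin of the first embryonic epithelium, stood at 184 FPKM in the untreated and 836 FPKM in the luciferase library and was listed at 0 in the knockdown. Slc5a11, a sodium-coupled inositol transporter, stood at 288 and 1136 FPKM in the controls and at 8.49 FPKM in the knockdown. Ptges, a prostaglandin E synthase, stood at 372 and 395 FPKM against 7.43 FPKM, and the matricellular glycoprotein gene Sparc at 719 and 281 FPKM against 11.1 FPKM. Tbx3, a T-box factor of pluripotent cells, stood at 72.7 and 120.3 FPKM against 1.34 FPKM, and the Groucho-family corepressor gene Tle4 at 40.1 and 175 FPKM against 1.13 FPKM. Gadd45a, a growth arrest gene of the DNA damage response, was listed at 0 in the knockdown, with 258 and 175 FPKM in the controls. Cryab, a small heat shock protein gene, stood at 179 and 238 FPKM in the controls and was listed at 0 in the other 3 libraries. Further genes named by rank were Grtp1, Tstd1, Tmem52, Pdzd3, Cd97, Cmbl, Trmu, Hsd17b6 and Lgals1, each listed at 0 in the knockdown, and Vrk2, Arrdc3, Gprc5a, Tmem64, Ccng2, Bhlhe40 and Pkp2, each at 5.54 FPKM or less there. In all, 835 genes were at least 4-fold lower in the knockdown than in each control, and 502 of them were listed at 0 in the knockdown.

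The genes higher in the knockdown than in both controls were ranked in the same way. Calml4, which encodes a calmodulin-like protein, stood at 0 and 4.79 FPKM in the untreated and luciferase libraries and at 468 FPKM in the knockdown. Iqcf1 stood at 0 and 4.69 FPKM against 448 FPKM, and Defb25, a beta-defensin gene, at 0 in both controls against 379 FPKM. Bfsp1, which encodes a filament protein of the eye lens, stood at 30.2 and 5.77 FPKM against 403 FPKM. Mkl2, a coactivator of serum response factor, stood at 2.24 and 1.7 FPKM against 166 FPKM, and Cbara1, a regulator of mitochondrial calcium uptake, at 43.8 and 39.9 FPKM against 1327 FPKM. Rom1, D5Ertd605e, AY761184, Asphd1, Wnt7b, Tmem160, Tslp and Tas2r107 were listed at 0 in both controls and lay between 95.6 and 209 FPKM in the knockdown. Others named by rank were Rnf215, Kbtbd13, Aqp11, Rpusd1, Fbxo36, AU019990, Klhl17, Pkn3 and Arhgdig. In all, 655 genes were at least 4-fold higher than in each control, and 253 of them were listed at 0 in both controls. With quantile normalization 740 genes were higher and 738 lower than in each control, so the excess of lower genes depends on scaling.

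The count of 1490 genes that differed from both controls lay inside the range found when other libraries were set apart. When each library in turn was set against each pair of the others, the 30 arrangements gave 1095 to 3096 genes, and 14 of them, the real one included, gave at least 1490. The arrangements with the untreated library set apart gave 2443 to 3096 genes, and those with the knockdown set apart 1430 to 1916. Each of the 14 either set the untreated library apart or held the knockdown. Among arrangements that did neither, the most was 1449 genes. The highest counts, 3096, 2929 and 2890, set the untreated library apart from pairs without the knockdown library, though each pair held an add-back library. Counts above 1490 were thus reached without the knockdown library, but only with the untreated library set apart. Among the 658 genes with a mean of at least 1000 FPKM, only 2 were lower and 2 were higher in the knockdown than in both controls. The 2 lower genes include H3f3b, a target of the knockdown.

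Of the gene lists, 4 stood apart on the same side against both controls in the knockdown. Both differences share the knockdown library, and such agreement is not particular to it. With the settings as reported, the H3.2 mRNA library was lower than both the luciferase and the knockdown library for ribosomal proteins, the respiratory chain and blood and endothelial markers. Regulators of trophectoderm and primitive endoderm, the first extraembryonic lineages, had a median of -1.63 on the log2 scale against the untreated library (percentile 0.07 of random lists) and -1.75 against the luciferase library (percentile 0). With no filter the former median was -0.66, and it still stood apart. Of the 21 members past the filter, 17 were lower and 3 higher than the mean of the controls. Besides Krt8, the endocytic adaptor gene Dab2 stood at 140 and 482 FPKM in the controls and 13.2 FPKM in the knockdown, E-cadherin (Cdh1) at 65.8 and 311 against 12.5 FPKM, and the water channel gene Aqp3 at 247 and 341 against 31.1 FPKM. Heat shock and unfolded protein response genes had medians of -1.13 (percentile 0.01) and -0.87 (percentile 0.07), with 25 of 31 members lower and 5 higher. Pdia6, a protein disulfide isomerase, stood at 1034 and 462 FPKM against 70.7 FPKM, and the stress regulators Xbp1 and Atf6 at 73.1 and 262 against 30.9 FPKM and at 20.9 and 98.8 against 6.28 FPKM. Atf5 went the other way, with 3.84 and 21.6 FPKM in the controls and 153 FPKM in the knockdown.

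Nuclear-encoded respiratory chain genes were higher in the knockdown, with medians of 0.73 (percentile 100) against the untreated and 0.87 (percentile 100) against the luciferase library, and 59 of 71 members higher. Ndufs5 stood at 400.5 and 71.3 FPKM in the controls and 1048 FPKM in the knockdown, Uqcrh at 142 and 482 against 1351 FPKM, and Ndufb2 at 116 and 195 against 744 FPKM. Cytosolic ribosomal protein genes had medians of 0.62 (percentile 100) and 0.44 (percentile 98.5), with 62 of 77 members higher, among them Rps27l at 2151 and 1432 FPKM against 5090 FPKM. These are short transcripts, and short transcripts were higher in the knockdown in general. Among genes with a mean of at least 50 FPKM, the rank correlation of transcript length with the difference was -0.20 against the untreated and -0.39 against the luciferase library. Against random lists matched also on length, the percentiles against the luciferase library were 92.2 for the respiratory chain and 2.86 for ribosomal proteins, so neither call held there, whereas those for the trophectoderm list were 0.11 and 0 and those for the heat shock list 0.02 and 0.23. With the length trend removed, the medians against the untreated library were 0.38 (percentile 99.6) for the respiratory chain and 0.17 (percentile 89.9) for ribosomal proteins.

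**Figure D2:**
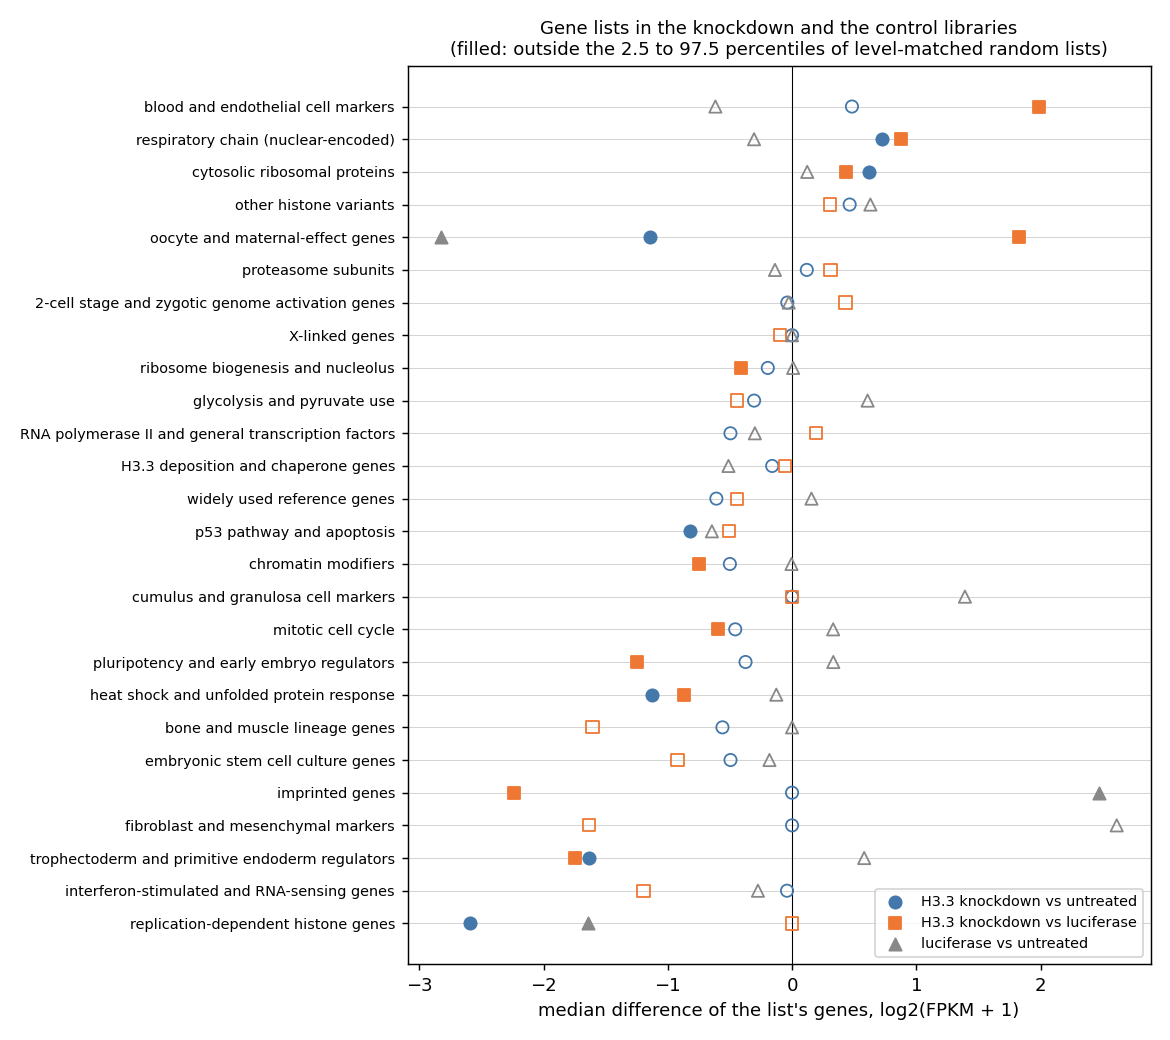
Median difference of each gene list (x axis, log2(FPKM + 1)) for the knockdown against the untreated library (circles), the knockdown against the luciferase library (squares) and the luciferase against the untreated library (triangles). Filled symbols stand apart from random lists matched on level, and 4 lists are filled on the same side against both controls.

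**Figure D3:**
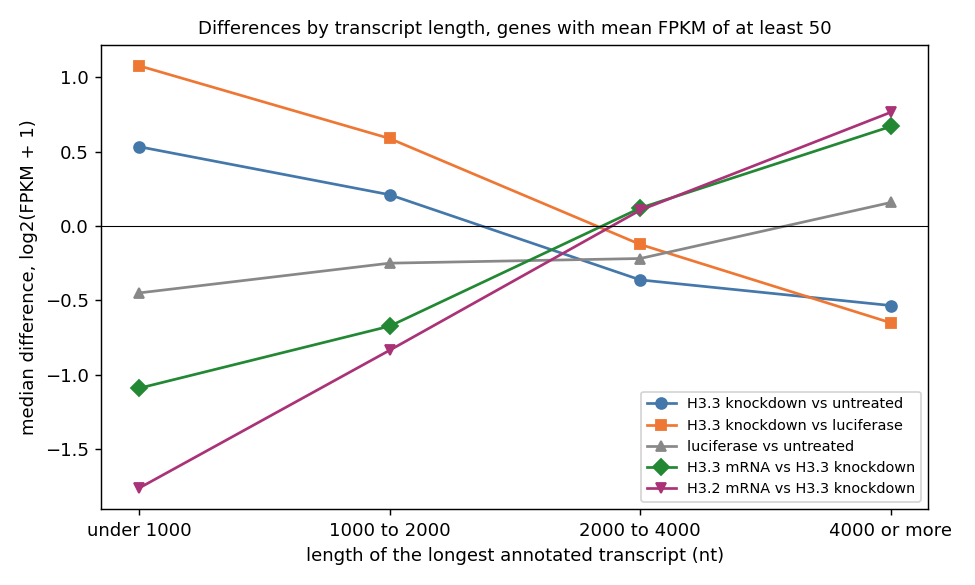
Median difference in log2(FPKM + 1) (y axis) over 4 classes of transcript length (x axis, nt) for genes with a mean of at least 50 FPKM; each line is 1 comparison. Under 1000 nt the knockdown was higher than the luciferase library by a median of 1.08, and at 4000 nt or more its median was -0.65.

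Other lists stood apart against 1 control, or on opposite sides of the controls. Oocyte and maternal-effect genes were lower in the knockdown than in the untreated library (median -1.15, percentile 0.02) and higher than in the luciferase library (1.83, percentile 100). Against the luciferase library, pluripotency and early embryo regulators were lower in the knockdown (median -1.25, percentile 0.02), and against the untreated library their median was -0.37 (percentile 13.6). Tbx3, Nanog, Prdm14 and Esrrb differed most: Nanog stood at 21.8 and 52.1 FPKM in the controls and Prdm14 at 40.3 and 12.9 FPKM, and both were listed at 0 in the knockdown. Imprinted genes were lower than in the luciferase library (-2.24, percentile 0.14), and blood and endothelial markers higher (1.99, percentile 99.8), a call that ended with no filter. Mitotic cell cycle genes (-0.60, percentile 0.31), chromatin modifiers (-0.75, percentile 0.66) and ribosome biogenesis genes (-0.41, percentile 0.88) were lower than in the luciferase library, and those 3 calls ended when lists were matched on length (percentiles 3.37, 8.98 and 5.12). Against the untreated library, p53 pathway and apoptosis genes (-0.82, percentile 1.56) and replication-dependent histone genes (-2.59, percentile 0.3) were lower, and both calls ended under an alternative. The p53 call ended over genes above 0 in every library, and the histone list of 13 members had a median of 1.01 with a filter at 5 FPKM. By gene, the knockdown differed at least 4-fold from the untreated library at 4266 genes (2211 higher, 2055 lower) and from the luciferase library at 3758 (1280 higher, 2478 lower). Upper-quartile scaling gave 2467 higher and 1681 lower for the former, and quantile normalization 1630 and 1954 for the latter. Of the 2211 and 1280 higher genes, 1212 and 440 were listed at 0 in that control. Of the 2055 and 2478 lower genes, 918 and 1608 were listed at 0 in the knockdown. The leading genes were Psmb8, Lgals1, Otos and Nfe2 (listed at 0 in the knockdown) and Chchd6, Aarsd1 and Snhg3 (listed at 0 in the untreated library) against the untreated library, and Slc16a5 and Emp2 (listed at 0 in the knockdown) and B9d1, Fam165b and Rbp7 (listed at 0 in the luciferase library) against the luciferase library.

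The 2 control libraries differed from each other at more genes than the knockdown did from either. The luciferase library was at least 4-fold higher than the untreated one at 3090 genes and lower at 1759, or 4849 in all. Of the 3090 genes, 1916 were listed at 0 in the untreated library, and of the 1759 genes 481 in the luciferase library. Quantile normalization gave 2432 higher and 2056 lower, and upper-quartile scaling 3388 and 1430. Oocyte and maternal-effect genes were the most displaced list, with a median of -2.82 (percentile 0) and 53 of 63 members lower in the luciferase library. Zar1, a maternal-effect gene of the egg-to-embryo transition, stood at 639 FPKM in the untreated and 5.76 FPKM in the luciferase library, and Oas1d, an oocyte-specific gene, at 571 and 6.55 FPKM. Mos, the kinase that holds oocytes in metaphase, and Oosp1, an oocyte-secreted protein gene, stood at 289 and 350 FPKM in the untreated library and were listed at 0 in the luciferase library. The linker histone gene of oocytes, H1foo, stood at 1925 and 74.8 FPKM. Imprinted genes were higher in the luciferase library (median 2.47, percentile 99.5), with Nnat, Plagl1, Meg3 and Slc38a4 listed at 0 in the untreated library and at 108, 49.2, 29.4 and 24.7 FPKM there. Fibroblast and mesenchymal markers had a median of 2.61 in this pair (percentile 96.8), within the range of random lists, and stood apart as higher at 5 FPKM and with length and GC trends removed. Replication-dependent histone genes were lower (-1.64, percentile 0.5), with a median of 1.45 at a filter of 5 FPKM, and that call held in 9 of 12 alternatives, with percentile 2.84 once the length trend was removed. The call on imprinted genes ended with filters at 5 and 50 FPKM. Single genes of high level in 1 control were listed at 0 in the other, among them Psmb8 and Otos in 1 direction and Icam4, Lhfpl5 and Slc25a41 in the other. The genes at least 4-fold from 1 control thus mix the treatment with this distance.

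The library labelled H3.3 mRNA was set against the knockdown, with the H3.3 genes themselves no higher in it. The list calls against the controls came from the same knockdown library. A list that lay low or high there can therefore move back here through that library alone. Chromatin modifiers were higher with H3.3 mRNA than in the knockdown (median 1.04, percentile 100, 43 of 53 members higher), with a median of 0.53 once the length trend was removed. The histone methyltransferase gene Ezh1 stood at 107 FPKM against 9.54 FPKM in the knockdown, and the deacetylase gene Hdac6 at 467 against 57.4 FPKM, whereas Dnmt3l, a cofactor of DNA methylation, stood at 110 against 953 FPKM. Ribosome biogenesis genes were higher (0.75, percentile 100), with the RNA polymerase I subunit gene Polr1a at 195 against 9.52 FPKM and Nop14 at 687 against 106 FPKM. Trophectoderm and primitive endoderm regulators were higher by a median of 1.06 (percentile 98.9), with 13 of 21 members higher and 7 lower. Krt18, a keratin gene, went the other way, listed at 0 against 48.7 FPKM. That call ended with no filter (median 0.00, percentile 42.5) and with a filter at 50 FPKM (0.70, percentile 91.8). The respiratory chain was lower (-1.03, percentile 0), and with the length trend removed its median was -0.25 (percentile 3.27). Bone and muscle lineage genes stood apart (percentile 99.7) with 3 of 5 members at least 4-fold higher, led by Col2a1 at 41.5 FPKM against a listed 0, and a median of 0.00 with no filter. Pluripotency regulators had a median of 0.51 (percentile 96.1), within the range of random lists, but stood apart when matched on length (percentile 98.7) and with the length trend removed (0.75, percentile 99.8). In all, 2150 genes were at least 4-fold higher and 1322 lower than in the knockdown. Of the 2150 genes, 1316 were listed at 0 in the knockdown, and of the 1322 genes 693 with H3.3 mRNA.

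Single genes were ranked by their difference between the H3.3 mRNA library and the knockdown. Fosl1, a component of AP-1, stood at 236 FPKM against 2.76 FPKM in the knockdown, and the pioneer factor gene Foxa1 at 107 against 2.35 FPKM. In the luciferase library Fosl1 stood at 1.63 FPKM. Cd24a, a cell surface glycoprotein gene, stood at 173 against 2.6 FPKM, the nuclear import factor gene Ipo7 at 137 against 1.96 FPKM, and Slc5a11 at 380 against 8.49 FPKM. Enpp3, Pdzd3, Cldn9, Acy1, Tnfsf13b, Stx1a, Ndrg1 and Ren1 stood at 113 to 254 FPKM and were listed at 0 in the knockdown. In the other direction, Cxcl10, an interferon-induced chemokine gene, and Sprr2e stood at 257 and 224 FPKM in the knockdown and were listed at 0 with H3.3 mRNA. Smarcd3, a subunit gene of BAF chromatin remodellers, stood at 196 FPKM in the knockdown and was also listed at 0. Rpusd3 stood at 563 FPKM in the knockdown and at 10.1 FPKM with H3.3 mRNA, and Tmem126a at 409 and 13.1 FPKM.

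The library labelled H3.2 mRNA was set against the knockdown in the same way. The same limit holds for lists that lay low or high in the knockdown. The H3.2 mRNA library had lower levels of ribosomal protein genes (median -1.74, percentile 0, 74 of 77 members lower) and of respiratory chain genes (-1.79, percentile 0, 64 of 71 lower). Rps27l stood at 717 FPKM against 5090 FPKM in the knockdown, Rps13 at 264 against 1669 FPKM, Ndufa4 at 218 against 2762 FPKM and Cox6c at 101 against 967 FPKM. Heat shock and unfolded protein response genes were higher (0.96, percentile 100, 23 of 31 members), with Hsph1 at 1048 against 172 FPKM, Atf6 at 99.3 against 6.28 FPKM and Atf3 at 41.8 FPKM against a listed 0. These 3 calls held in all 14 alternatives run on lists, but with the length trend removed the medians were -0.31 for ribosomal proteins, -0.42 for the respiratory chain and 1.05 for heat shock genes. Mitotic cell cycle genes (0.39, percentile 99.8), ribosome biogenesis genes (0.15, percentile 99.4), chromatin modifiers (0.71, percentile 97.9) and blood and endothelial markers (-0.89, percentile 2.45) also stood apart, and those 4 calls ended when lists were matched on length (percentiles 93.4, 94.9, 76.0 and 13.1). Among single genes, Usp47, a deubiquitinase gene, stood at 259 against 6.25 FPKM, the histone acetyltransferase gene Myst4 at 113 against 2.46 FPKM and the mitochondrial elongation factor gene Gfm2 at 88.6 against 0.65 FPKM. Skap2, Opa3, Casp2 and Nanos3 were listed at 0 in the knockdown and stood at 154, 136, 113 and 91.1 FPKM. Mlana, Ift27, Prr23a, Ifitm1 and Glod5 stood at 159 to 184 FPKM in the knockdown and were listed at 0 here. In all, 2558 genes were at least 4-fold higher and 1198 lower, and quantile normalization gave 1889 and 1543. Of the 2558 genes, 1567 were listed at 0 in the knockdown, and of the 1198 genes 430 with H3.2 mRNA.

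The H3.3 mRNA and H3.2 mRNA libraries were then compared by gene. Spic, an Ets-family transcription factor gene, stood at 2136 FPKM with H3.3 mRNA and 80.6 FPKM with H3.2 mRNA, with 644 FPKM in the untreated, 1955 FPKM in the luciferase and 151 FPKM in the knockdown library. Fosl1 stood at 236 against 3.44 FPKM, Foxa1 at 107 against 1.99 FPKM, and Tbx3 at 66.9 against 3.09 FPKM. The trophectoderm factor gene Tead4 stood at 814 against 154 FPKM, but its list did not stand apart (median -0.21, percentile 33.5). Ckmt1, a mitochondrial creatine kinase gene, stood at 129 against 3.24 FPKM and the adhesion molecule gene Pecam1 at 647 against 40.4 FPKM. Prdm14 stood at 24.8 FPKM and was listed at 0 with H3.2 mRNA. In the other direction, Zfp451 stood at 1.62 with H3.3 mRNA against 113 FPKM with H3.2 mRNA, Iqca at 5.33 against 207 FPKM, the growth factor gene Fgf1 at 9.48 against 210 FPKM and Dab2 at 3.51 against 67.4 FPKM. AI506816, Isoc2b, St6galnac6, Comp, Cox7a1, Duoxa2, Palm3 and Apobec2 were listed at 0 with H3.2 mRNA, and Tubd1, Cklf, Apeh, Rab19, Oxr1, Efcab4b, Gstm4, Sytl3 and Stard5 at 0 with H3.3 mRNA. In all, 1101 genes were at least 4-fold higher and 1661 lower with H3.3 mRNA, and quantile normalization gave 1323 and 1366. Of the 1101 genes, 566 were listed at 0 with H3.2 mRNA, and of the 1661 genes 1074 with H3.3 mRNA.

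By list, ribosomal protein genes were higher with H3.3 mRNA than with H3.2 mRNA (median 1.09, percentile 100, 72 of 77 members), among them Rps15 at 7764 against 1703 FPKM and Rpl39 at 1897 against 300 FPKM. With the length trend removed their median was 0.61, and that of the respiratory chain 0.30. The respiratory chain (0.68, percentile 100), blood and endothelial markers (2.81, percentile 100, 8 members), ribosome biogenesis (0.54, percentile 98.6), RNA polymerase II and general transcription factors (0.49, percentile 98.0) and pluripotency regulators (0.43, percentile 97.9) were also higher. Heat shock and unfolded protein response genes were lower (-0.49, percentile 0.02), with Asns at 119 against 562 FPKM and Pdia6 at 51.2 against 242 FPKM, and so were mitotic cell cycle genes (-0.24, percentile 0.27), with Plk4 at 64.7 against 278 FPKM. The pluripotency call ended in 8 of 14 alternatives, with percentile 95.2 for lists matched on GC content, and the ribosome biogenesis call in 3, among them quantile normalization (0.15, percentile 89.3) and removal of the length trend (0.30, percentile 97.4). The call on RNA polymerase II and general transcription factors ended with the length trend removed (0.27, percentile 93.8) and at 50 FPKM, that on the respiratory chain with both trends removed, and that on blood and endothelial markers with no filter. Against the untreated library, the H3.3 mRNA library had medians of -0.04 for ribosomal proteins and -0.26 for the respiratory chain, and neither stood apart as reported. Against luciferase, the H3.2 mRNA library had medians of -1.19 and -0.67 for them. Higher values with H3.3 mRNA for these lists are therefore no rise above the untreated library. The 2 add-back libraries carry different source names, so the added mRNA and a possible batch cannot be told apart.

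**Figure D4:**
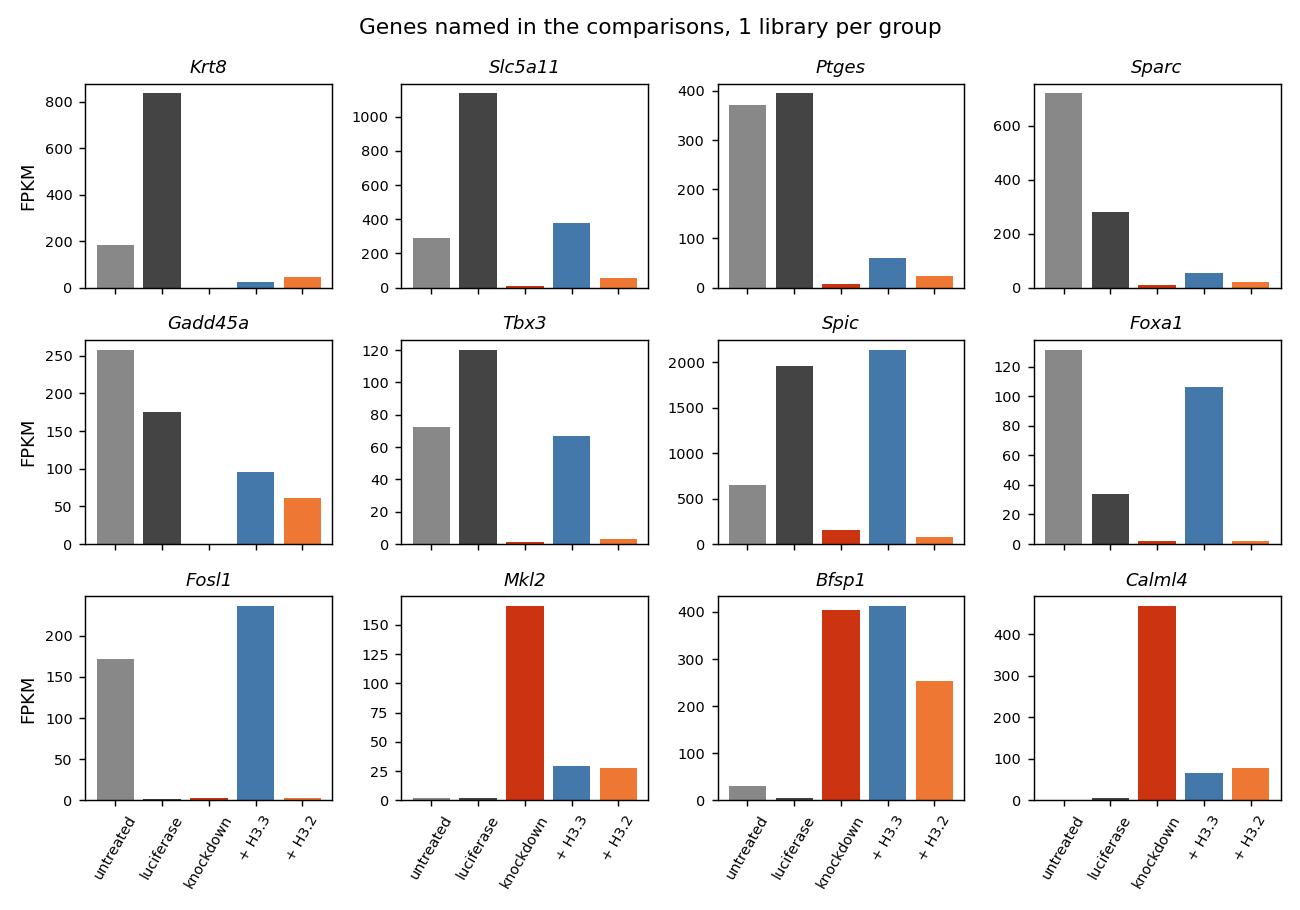
FPKM (y axis, from 0, own scale per panel) of 12 named genes in the 5 libraries, 1 bar per library without replicates. Spic, Tbx3, Foxa1 and Fosl1 are low in the knockdown and with H3.2 mRNA and high with H3.3 mRNA, and Krt8, Ptges and Sparc stay below both controls in the 3 knockdown libraries. Fosl1 is also low in the luciferase control.

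The share of genes on the control side was counted in both add-back libraries. Of the 835 genes lower in the knockdown than in both controls, 572 (68.5%) lay on the control side with H3.3 mRNA and 578 (69.2%) with H3.2 mRNA, and 449 did so in both. Pdzd3 and Gadd45a, both listed at 0 in the knockdown, stood at 163 and 95.3 FPKM with H3.3 mRNA and at 103 and 61.2 FPKM with H3.2 mRNA. Krt8 stood at 22.5 and 44.8 FPKM, under either control. Of the 655 genes higher in the knockdown, 394 (60.2%) lay on the control side with H3.3 mRNA and 338 (51.6%) with H3.2 mRNA, and 247 did so in both. The gap goes with listed zeros, since 271 (41.4%) of these genes were listed at 0 with H3.3 mRNA and 190 (29.0%) with H3.2 mRNA. The shares were 44.1% and 45.4% over genes above 0 in every library, and 65.9% and 65.1% with pseudocount 5. Bfsp1 stayed at 412 FPKM with H3.3 mRNA and 252 FPKM with H3.2 mRNA. Against the untreated control alone, the shares among lower genes were 43.7% and 46.2%, and 41.4% and 40.8% of the lower genes lay within 2-fold of the mean of both controls.

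Pairs with the same source name were compared to set that possible batch aside. With H3.2 mRNA, 1369 genes were at least 4-fold higher and 1293 lower than with luciferase, the fewest of the 8 pairs compared. Of the 1369 genes, 716 were listed at 0 with luciferase, and of the 1293 genes 755 with H3.2 mRNA. Trophectoderm and primitive endoderm regulators (-1.06, percentile 0), pluripotency regulators (-1.02, percentile 0.01), ribosomal proteins (-1.19, percentile 0, or -0.61 with the length trend removed), fibroblast and mesenchymal markers (-3.01, percentile 0) and imprinted genes (-0.81, percentile 0.61) were lower. The fibroblast call ended with no filter, and the imprinted call over genes above 0 in every library and with a filter at 50 FPKM. Id3, an inhibitor of helix-loop-helix factors, stood at 29.6 FPKM against 1576 FPKM and Smpdl3a at 5.51 against 341 FPKM. Oocyte and maternal-effect genes (1.70, percentile 100) were higher, with the oocyte growth factor gene Bmp15 at 112 against 2.13 FPKM, and so were H3.3 deposition and chaperone genes (0.73, percentile 99.1). With H3.3 mRNA, 2703 genes were at least 4-fold higher and 1816 lower than in the untreated library. Of the 2703 genes, 1556 were listed at 0 in the untreated library, and of the 1816 genes 660 with H3.3 mRNA. Upper-quartile scaling gave 3008 higher and 1481 lower. Oocyte genes (-1.42, percentile 0), replication-dependent histone genes (-2.78, percentile 0.05), p53 pathway genes (-0.87, percentile 0.98) and bone and muscle lineage genes (-2.34, percentile 1.24) were lower, and ribosome biogenesis (0.36, percentile 99.8) and imprinted genes (1.36, percentile 98.3) higher. The imprinted call held in 5 of 14 alternatives, the bone and muscle call ended with no filter, and the histone call ended at 5 FPKM. Bms1, a ribosome assembly factor gene, stood at 394 against 3.92 FPKM, whereas Gnmt, Gmpr, Pdlim4 and Rims3 were listed at 0 with H3.3 mRNA and stood at 337 FPKM or more in the untreated library.

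Over all genes past the filter, differences from a control did not run in parallel between pairs that share no library. Across genes, the knockdown to untreated ratio and the H3.2 mRNA to luciferase ratio had a Pearson's r of 0.019 and a Spearman's rho of 0.00084, and with the H3.3 mRNA to luciferase ratio these were -0.013 and -0.00031. The knockdown to luciferase ratio had r = -0.078 and rho = -0.11 with the H3.3 mRNA to untreated ratio, and r = -0.086 and rho = -0.13 with the H3.2 mRNA to untreated ratio. These 4 correlations are across genes, which are not replicates, and pool genes of all levels. Rank correlations with transcript length were -0.24 for the knockdown to luciferase ratio and 0.13 for the H3.3 mRNA to untreated ratio. By list, trophectoderm and primitive endoderm regulators were lower both in the knockdown against untreated (-1.63) and with H3.2 mRNA against luciferase (-1.06). Oocyte, ribosomal protein and respiratory chain genes stood apart in both pairs but on opposite sides. The 458 X-linked genes past the filter had a median of 0 in the knockdown against the untreated library (percentile 50.1) and of -0.10 against the luciferase library (percentile 63.9), and with the settings as reported they did not stand apart in any of the 8 pairs.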

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

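The tests of the untreated pool and of the source name were chosen only after the pattern was seen, and the match on transcript length is an alternative added after the data were seen. Oocyte and maternal-effect genes lay on opposite sides of the 2 controls in the knockdown, with a median log2 difference of -1.15 against the untreated and 1.83 against the luciferase library, and the difference was not tested. A transcript length trend does not account for the distance between the controls, since the luciferase minus untreated median lay at percentile 0 among lists matched on level and length, nor does the source name as the whole cause, since the list stood apart within names in all 14 alternatives (H3.2 mRNA against luciferase by 1.70, knockdown against untreated). The luciferase library also lay below the knockdown by 1.83 and below the H3.2 mRNA library by 1.70. Oocytes or undeveloped embryos in the untreated pool cannot enter these pairs, which lack that library, so the 2 values are no test of such a pool. On the untreated side such a pool may be the source but cannot be told apart from slower clearance of oocyte mRNA or the treatment with 1 library per group, since the 53 of 63 members higher there than in the luciferase library restate the pattern.

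Some genes also lay at least 4-fold above 1 control and 4-fold below the other in the knockdown, and these differences were not tested. Gpc4 stood at 46.4 FPKM in the knockdown, 527 in the luciferase and 0 in the untreated library, and Plk5 at 10.1, 533 and 0 FPKM. Slc30a3 stood at 34.3 FPKM in the knockdown, 0 in the luciferase and 469 in the untreated library, and Tmem25 at 3.96, 0 and 405 FPKM. Raver1-fdx1l, a readthrough of neighbouring genes with shared reads, stood at 4.34, 0.02 and 398 FPKM. AI506816 was opposite between the add-back libraries, with 5.2 FPKM in the knockdown, 441.8 FPKM with H3.3 mRNA and 0 with H3.2 mRNA. In all, 144 genes were opposite against the 2 controls and 23 between the add-back libraries.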

How the results depend on the processing

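The filter at 50 FPKM, the removal of length and GC trends and the matches on length and GC content were chosen after seeing the data. No paired analysis was possible because no label pairs the libraries. Leaving out a replicate was not possible with 1 library per group, and taking the highest of several values per symbol was not run because no symbol has several. The depth is unknown, so no limit from counts is given. Of 58 list calls, 26 held in all alternatives run on them and 38 in all planned ones. The median of 48 of the 58 moved by over 1.5 times in at least 1 alternative, as it did for 16 of the 26. Of 971 values of named genes past 4-fold as reported, the 4-fold difference was lost for 164 with pseudocount 5, 122 with length and GC trends removed, 111 with the length trend removed, 69 with quantile normalization, 22 with upper-quartile scaling, 16 with median-ratio scaling and 1 with pseudocount 0.1, and none reversed. Below, a count is given where it changed by over 1.5 times and a share where it left the 95% binomial interval of the share as reported, and smaller changes are not printed. By these limits median-ratio and upper-quartile scaling gave no such count or share, nor did 50 nearest genes, run on lists alone, though 2, 2 and 4 further list results came to stand apart with them. Scaling shifted the median of genes above 0 in the compared libraries by 0.18 (median ratio), 0.34 (upper quartile) and 0.11 (quantile) for the knockdown against the untreated library and by 0.15 (quantile) against the luciferase library. It shifted the luciferase against the untreated library by 0.11 and 0.34, and H3.3 mRNA against untreated by 0.10 and 0.33 (median ratio and upper quartile). For the values below the cause was not tested, except that stricter filters and folds leave fewer genes.

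Counts are given in 1 order: knockdown lower and higher than both controls, then knockdown against untreated, knockdown against luciferase, luciferase against untreated, H3.3 mRNA against knockdown, H3.2 mRNA against knockdown, H3.3 against H3.2 mRNA, H3.2 mRNA against luciferase and H3.3 mRNA against untreated. They were 1879, 1487, 7195, 7107, 7886, 6720, 7217, 5657, 5637 and 7428 genes at 2-fold, and 403, 322, 2642, 1970, 2858, 1991, 1924, 1432, 1353 and 2707 at 8-fold. Over genes above 0 in every library they were 323, 152, 1935, 1351, 2015, 1237, 1406, 730, 701 and 1995, and with a mean of at least 50 FPKM 259, 117, 1392, 1005, 1411, 902, 951, 467, 450 and 1399. With pseudocount 5, without knockdown against untreated, which stayed within 1.5 times, they were 372, 387, 1995, 2926, 1971, 1986, 1162, 1102 and 2949. A filter at 5 FPKM gave 1829 for H3.3 against H3.2 mRNA and 1725 for H3.2 mRNA against luciferase. The untreated control alone gave 2055 lower and 2211 higher, and the luciferase control alone 2478 and 1280.

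Shares on the control side among genes lower in the knockdown, for H3.3 and H3.2 mRNA, became 43.7% and 46.2% with the untreated control alone, 57.3% and 62.1% with the luciferase control alone, 41.4% and 40.8% within 2-fold, 64.8% and 63.0% with quantile normalization, and 62.4% and 61.2% with length and GC trends removed. Past its interval, the H3.3 mRNA share moved to 73.4% over genes above 0 in every library and 71.8% at 50 FPKM. Past its interval, the H3.2 mRNA share moved to 75.5% with pseudocount 0.1, 61.8% with pseudocount 5 and 61.8% with the length trend removed. Among genes higher in the knockdown the shares became 53.7% and 42.9% with pseudocount 0.1, 65.9% and 65.1% with pseudocount 5, 55.0% and 45.2% at 5 FPKM, 44.1% and 45.4% over genes above 0 in every library, 66.1% and 57.8% at 8-fold, 33.6% and 27.2% with the untreated control alone, 39.8% and 33.4% within 2-fold, and 48.7% and 39.3% at 50 FPKM. Past its interval, the H3.2 mRNA share moved to 60.8% with quantile normalization, 55.5% with the luciferase control alone, 62.9% with the length trend removed and 61.5% with both trends removed.

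Replication-dependent histone genes reversed at 5 FPKM, to medians of 1.01 for the knockdown and 1.45 for the luciferase against the untreated library. Ribosomal proteins in the knockdown against luciferase reversed to -0.33 with the length trend removed and -0.29 with both trends removed. X-linked genes came to stand apart at 5 FPKM for H3.2 mRNA against knockdown (-0.0027) and H3.3 against H3.2 mRNA (0.037), over genes above 0 in every library for these pairs and H3.2 mRNA against luciferase (-0.16, 0.12 and -0.13), and matched on GC content for the same 3 pairs (0, 0 and -0.0057). They did so for H3.2 mRNA against luciferase at 50 FPKM (-0.36) and with the length trend removed (-0.12), and with both trends removed for H3.3 mRNA against knockdown (0.079), H3.3 against H3.2 mRNA (0.28) and H3.2 mRNA against luciferase (-0.19). The number of lists apart became 3 for H3.3 mRNA against knockdown with no filter and at 50 FPKM, and 8 matched on length. For luciferase against untreated it became 5 at 5 FPKM, with the length trend removed and matched on length, and 6 with both trends removed. For H3.3 mRNA against untreated it became 3 over genes above 0 in every library and at 50 FPKM. For H3.2 mRNA against knockdown it became 3 with the length trend and 4 with both trends removed, and for H3.3 against H3.2 mRNA 5 with the length trend removed. For the knockdown against luciferase it became 6 matched on length, where 2 lists stood apart on the same side against both controls.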

Other observations

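Tests chosen only after the result was seen were those of ribosomal and respiratory chain genes against the untreated library and of the whole H3.3 mRNA library, and all matches on length or GC content and removals of trends. Genes of the 2-cell stage and genome activation did not stand apart in any of the 8 pairs with the settings as reported, with medians of -0.04 (percentile 43.1) and 0.43 (percentile 95.7) for the knockdown against the untreated and luciferase libraries. Matched on length, they stood apart for H3.3 mRNA against the knockdown (0.47, percentile 99.0). Arg2, an arginase gene, stood at 993 FPKM in the knockdown, with 332 and 73.9 FPKM in the controls. Interferon-stimulated and RNA-sensing genes had medians of -0.04 (percentile 20.4) and -1.20 (percentile 5.44), with the regulators Irf1 at 411 and 81.8 against 21.3 FPKM and Irf9 at 462 and 89.7 against 30.7 FPKM, and stood apart as lower than in the untreated library with a filter at 5 FPKM. Proteasome subunits (0.12 and 0.31), embryonic stem cell culture genes (-0.50 and -0.92), cumulus and granulosa cell markers (0 and 0) and widely used reference genes (-0.61 and -0.44) did not stand apart in any pair either with these settings, though each did under some alternative. The reference genes were lower in the knockdown with the length trend removed, by -0.76 (percentile 0.22) against the untreated and -0.80 (percentile 0.34) against the luciferase library, and with H3.3 mRNA by -0.58 (percentile 1.32) against the untreated library. The 4 neural lineage genes past the filter had medians of 0 and -1.79 and were too few for a percentile.

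Further lists stood apart in the H3.2 mRNA library against luciferase. Glycolysis and pyruvate genes were lower (-0.62, percentile 1.18), with the glucose transporter genes Slc2a3 at 37.7 against 449 FPKM and Slc2a1 at 40.7 against 342 FPKM, and that call ended with quantile normalization and at 50 FPKM. With the length trend removed they were also lower in the knockdown than in the luciferase library (-0.75, percentile 0.57). Other histone variants were lower (-0.95, percentile 1.67), a call held in 6 of 14 alternatives, with the macroH2A gene H2afy at 29.3 against 129 FPKM and the centromeric variant gene Cenpa at 336 against 767 FPKM. H3.3 deposition and chaperone genes were higher in all 14 alternatives, with Asf1a at 65.8 against 14.3 FPKM and Hira at 162 against 73.6 FPKM. In the same pair the respiratory chain was lower (-0.67, percentile 0.02), which ended with the length trend removed, and so were blood and endothelial markers (-1.43, percentile 2.13), held in 5 of 12 alternatives.

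The gene groups of the knockdown were set against its length trend. Trophectoderm and primitive endoderm regulators stayed lower at percentile 0.11, and heat shock genes at percentile 0.23, against the control nearer the middle when matched on length, which argues against length as the whole cause. Widely used reference genes were also lower against both controls with the length trend removed, as given above, so being lower there is not particular to these lists. Ribosomal proteins at percentile 2.86 and the respiratory chain at percentile 92.2 against luciferase lost their calls, and with the trend removed their medians went from 0.44 to -0.33 and from 0.87 to 0.14, so the length trend may account for these. Against the untreated library the respiratory chain was at percentile 99.8 when matched and 99.6 with the trend removed, but its median went from 0.73 to 0.38, so length is argued against only as the whole cause. Ribosomal proteins had percentiles of 99.3 and 89.9 there, and for them the trend and a difference in the group cannot be told apart because the corrections differ. Matched on length, they also stood apart as higher in the luciferase than in the untreated library (0.12, percentile 99.9). A shift of this list against the untreated library is therefore not particular to the knockdown. The add-back libraries had H3.3 transcript sums below that of the knockdown. Over genes with a mean of at least 50 FPKM, the rank correlation of length with their difference from the knockdown was 0.42 (H3.3 mRNA) and 0.51 (H3.2 mRNA). The trend therefore did not go with low H3.3 transcripts in every library. A lower yield of long transcripts in the knockdown library and an effect of the knockdown both stay open.

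Pluripotency regulators were higher with H3.3 than with H3.2 mRNA, at percentile 97.9, close to the limit of the range of random lists. The call ended at percentile 97.1 when matched on length and 95.2 when matched on GC content, but the median went from 0.43 to 0.33 with the length trend removed and to 0.30 with both trends removed, so a sequence property may be part of it and is neither shown nor excluded. A library with H3.3 mRNA that lies closer to the controls as a whole also stays open: the shares on the control side with H3.3 and H3.2 mRNA were 68.5% and 69.2% of the genes lower in the knockdown and 60.2% and 51.6% of those higher, but the latter were 44.1% and 45.4% over genes above 0 in every library and 65.9% and 65.1% with pseudocount 5. Of those higher genes 41.4% and 29.0% were listed at 0. The source names and the added mRNA differ together, so an effect of the histone variant stays open and untested.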
